A study of Mus musculus with 9 samples.

How the data were processed

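RNA was measured by polyA RNA-seq in dissected hippocampal tissue of 9 adult male C57BL/6NCrl mice, an inbred mouse strain. Per the labels, a recombinant adeno-associated virus carrying a short hairpin RNA (shRNA) was injected into the dorsal hippocampus at 8 weeks of age, and the tissue was taken 3 weeks later. The infected area was found by its mCherry fluorescence, a red marker protein. Libraries were made from 1.5 µg of total RNA and did not keep the strand of the transcript. The groups were a control shRNA without a target, shRNA A and shRNA B against Camta1, with 3 animals in each according to the series' design. Libraries are named by group and by the number in their label.

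The authors deposited a table of whole-number read counts per Ensembl gene, raw per the file headers. The submitters' processing notes name TopHat 1.4.1, SAMtools 0.1.19, HTSeq 0.6.1, DESeq2 1.4.5, R 3.1.1 and the mouse genome build mm9, without their settings. The gene annotation behind the counts is not given in the sources used here. Beside the counts, the authors' deposited table holds a mean normalized signal per gene, log2 fold changes of each shRNA against control with their standard errors, and a test score of a likelihood ratio test. It also holds the p-value and adjusted p-value of that test, per the file headers. Because the libraries carry no strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads of near-identical members of a family, such as the Ifit, Oas, Gbp, H2 and Hba genes, could be split between them or lost, so levels of single members are uncertain.

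The table lists 31804 genes, of which 8730 had 0 counts in every library. A symbol came from the table for 20478 genes and from a list of gene names for 6546 more, matched on the Ensembl identifier, and 4780 kept the identifier alone. The annotation at hand was of build GRCm38 (GENCODE M21), so no coordinates from it are given and chromosomes are those in the deposited table. It served to find exons that overlap those of another gene by at least 100 bases, which 46 of 219 named genes do, 15 of them with a protein-coding gene. Cdkn1a, Nos1, Aldh1l1, Psmb8, Rtp4, Cxcl10, Stard5 and Gpr17 are among the 46. Of the columns with values per sample, 0 could not be matched to a label.

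Counts were analysed as deposited with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 16438, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test with robust estimation on all 9 libraries, which share one estimate of the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were shRNA A minus control, shRNA B minus control, the mean of both shRNAs minus control, and shRNA B minus shRNA A. All tests are two-sided. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, counts brought to a common library size with the TMM factors, given as mean ± SD of 3 libraries. The common biological coefficient of variation was 9.4%, with a median of 6.31 prior degrees of freedom.

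Library totals lay between 29123744 and 38189288 counts, so that 1 read stood for 0.0262 to 0.0343 CPM and 3 reads for 0.0786 to 0.103 CPM. Floors of this kind cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries of a group matched within counting noise, as files of one library deposited again would, with a chi-square per degree of freedom between 7.9 and 20.9 over genes with at least 10 counts. Whether libraries came from separate animals rests on the series' design and not on this check.

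On simulated counts with 3 libraries per group, the test for shRNA A recovered 73.1% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, over 16324 genes. For shRNA B the shares were 71.6%, 94% and 100% over 16338 genes, and for the mean of both shRNAs 76.1%, 94% and 100% over 16329 genes. For shRNA B minus shRNA A they were 73.1%, 92.5% and 98.5% over 16321 genes. Each simulation gave 11 or 12 false calls among 184 to 191. The changed genes, 66 or 67 for each fold, all had a mean of at least 1 CPM. Noise was drawn gene by gene from the fitted spread, without variation shared between the genes of an animal. The shares therefore need not hold for genes at lower levels or for the real libraries. In the simulation of the mean contrast, camera called the raised list and 0 of 40 unchanged lists. Its genes varied independently and the unchanged lists were drawn at random, so it cannot show how often camera calls unchanged lists of correlated genes. In the data, the correlation between genes estimated for the mean contrast was 0.803 in the interferon list and 0.913 in the oligodendrocyte list.

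Before the data were examined, 32 lists of genes, the named-gene rule, the designs and the alternatives were fixed. The lists cover synapses, ion channels, calcium signalling, activity, interferon, p53 and cell death, glia, vessels, meninges, choroid plexus, regions and cell types of the hippocampus, neighbouring brain regions, blood, ribosomes, mitochondria, neuropeptides, matrix and microRNA processing. They hold 843 genes, 829 of which were found and 811 tested; a gene may stand in more than 1 list. Lists were tested with camera, run on edgeR's counts with their fitted spread, at a preset inter-gene correlation of 0.01. It asks whether the genes of a list shift up or down on average relative to the other genes. P-values were adjusted over the 32 lists within a contrast. The same test was run with a correlation estimated from the data, where 0 lists passed in any contrast. A list's median, mean and test differed in sign in 12 of 128 results, of which 0 passed. The fry test asks whether the genes of a list move, on balance, one way, without comparing them with other genes, and its mixed form asks whether they change in either direction. A list score of a library is the mean log2 CPM of its tested genes, with a prior count of 2, minus the control mean.

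The rule for named genes takes Camta1, Camta2, Nppa and Fbxl4. It adds up to 12 rising and 12 falling genes called with both shRNAs whose 6 knock-down libraries all lie on one side of the 3 controls. Per contrast it takes up to 5 rising and 5 falling called genes without overlap between the groups and with a mean of at least 1 CPM, ranked by fold change. Per list it takes up to 4 members with the smallest adjusted p in the contrast described. Predicted genes with Gm or Rik symbols are counted and not named. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here.

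Alternatives were other scalings (RLE, upper quartile, library size only), no low-count filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit to the groups compared alone, robust estimation off, an adjusted p of 0.1, a 1.5-fold minimum, a replicate block, and each library left out in turn. An exact permutation of the list scores was added after the data were seen. Chance values for 2 comparisons that share their controls came from 60 simulations of unchanged groups. Other splits of the libraries were refitted with 10, 84 or 100 splits; in the 84 splits into 3 and 6, the 6 were put at random into 2 groups of 3. Principal components used the 2000 genes of highest variance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Transcript isoforms and reads were not analysed here.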

Results

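The series asks which genes of the adult mouse hippocampus depend on Camta1, which encodes a calmodulin-binding transcription activator. Transcript levels were measured in 9 libraries, 3 from mice with a control shRNA and 3 each from mice with shRNA A or shRNA B, different hairpins directed against Camta1. A short hairpin RNA lowers the mRNA it matches. Total counts were 29123744, 32406247 and 31693719 in the control libraries. They were 31550143, 30807591 and 30970850 with shRNA A, and 38189288, 31178068 and 31280769 with shRNA B. The 10 highest genes took 5.02% to 5.76% of a library's counts, and mitochondrial genes took 2.88% to 3.51%. The first principal component held 29.4% of the variance and placed the controls between -16.4 and -11.4, shRNA A between -10.2 and 2.95, and shRNA B between 9.15 and 25.4. On the second component, with 18% of the variance, shRNA A replicate 3 had the highest value, 19.9.

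Camta1 mRNA (ENSMUSG00000014592, chromosome 4) was the target of both hairpins. It stood at 427, 455 and 442 CPM in the control libraries, at 230, 174 and 254 CPM with shRNA A, and at 239, 145 and 266 CPM with shRNA B. The level was 49.8% ± 9.4 (SD, n = 3) of the control mean with shRNA A and 49.1% ± 14.3 (SD, n = 3) with shRNA B, and all 6 knock-down libraries lay below all 3 controls. An exact two-sided permutation test of 6 libraries against 3 gave p = 0.0119. Exact tests of each shRNA gave p = 0.1, and in each case this is the smallest p these numbers allow. In edgeR's test the log2 fold change was -1.01 ± 0.22 (SE) with shRNA A (adjusted p = 0.388), -1.02 ± 0.22 with shRNA B (adjusted p = 0.0776). It was -1.02 ± 0.18 for the mean of both (edgeR adjusted p = 0.107), so Camta1 did not pass the threshold. DESeq2 did call it, with adjusted p = 0.0152, 0.00174 and 0.000365, within ranges over all alternatives of 0.0128 to 0.946, 0.00174 to 0.239 and 0.000365 to 0.427. Without shRNA B replicate 2, the library with the lowest Camta1, edgeR's adjusted p was 0.015, 0.0367 and 0.00647. In the authors' deposited table Camta1 has log2 fold changes of -1.01 and -1.03 with an adjusted p of 0.000358.

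Camta2, the other mouse member of the family, had 836 ± 139, 862 ± 49.6 and 852 ± 23.4 CPM in control, shRNA A and shRNA B (SD, n = 3), with log2 fold changes of 0.05 and 0.03. Without control replicate 1 these were -0.08 and -0.10, so no direction is given. Nppa, which encodes atrial natriuretic peptide, was near 0.484 ± 0.0996 CPM in controls, with log2 fold changes of 0.31 ± 0.27 and 0.15 ± 0.27 (SE). Without shRNA B replicate 1 the second was -0.02. Fbxl4, an F-box gene, was at 12.6 ± 0.0932 CPM in controls and its log2 fold changes of 0.03 and -0.02 lay within their SE of 0.079 and 0.078. With scaling by library size alone the second was 0.003, and without shRNA B replicate 2 it was 0.02. None of these 3 genes passed edgeR's test in either contrast, with adjusted p between 0.846 and 0.959.

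**Figure D1:**
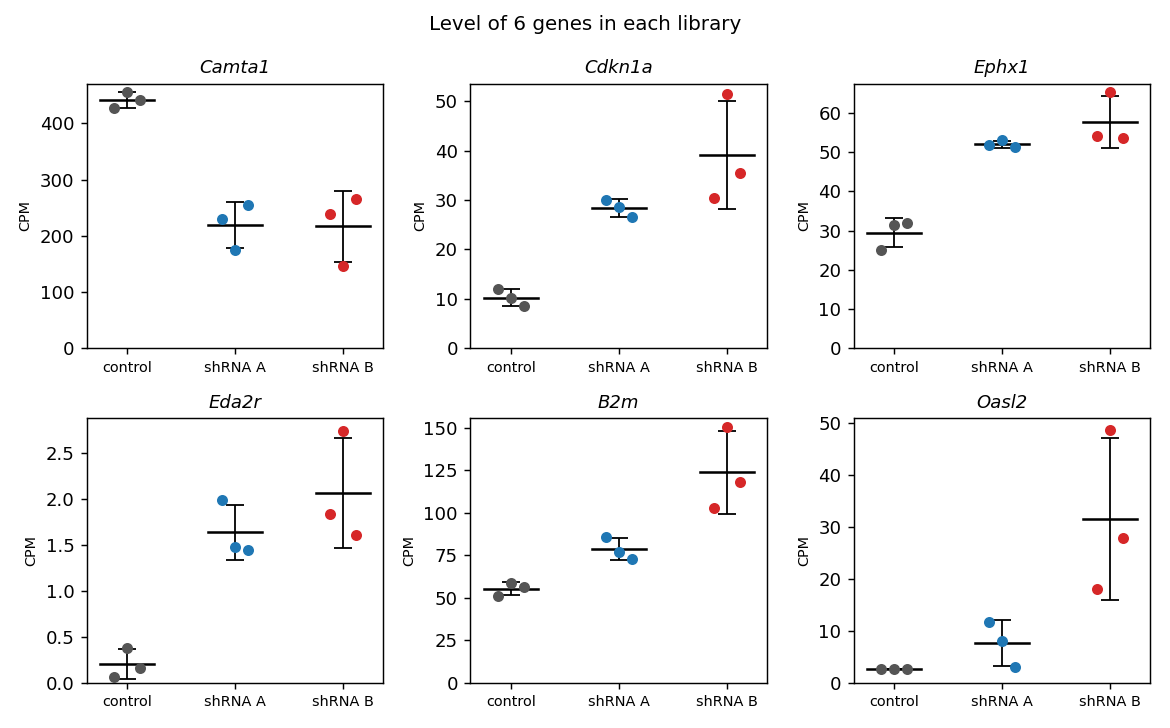
Levels of 6 genes in CPM (vertical axis, from 0) in each library of the 3 groups (points, spread sideways for legibility), with the mean (line) and SD (bars, n = 3). Camta1 lies at 427 to 455 CPM in the controls and at 145 to 266 CPM in the 6 knock-down libraries, while the mean of Oasl2 goes from 2.7 CPM in controls to 7.7 with shRNA A and 31.6 with shRNA B.

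With shRNA A, 4 genes rose and 0 fell in edgeR's test. Ephx1 (ENSMUSG00000038776, chromosome 1), the microsomal epoxide hydrolase, went from 29.5 ± 3.78 to 52.1 ± 0.888 CPM (SD, n = 3), a log2 fold change of 0.82 ± 0.099 (SE, adjusted p = 0.0386). Eda2r (ENSMUSG00000034457, chromosome X), a receptor of the tumour necrosis factor family, went from 0.202 ± 0.162 to 1.63 ± 0.301 CPM, a log2 fold change of 2.97 ± 0.41 (adjusted p = 0.039). In control replicate 1 Eda2r stood at 0.0678 CPM, below the level of 3 reads there, 0.103 CPM. Its log2 fold change ran from 2.585 to 3.792 over the alternatives. Mmp2 (ENSMUSG00000031740, chromosome 8), a matrix metalloproteinase, rose from 2.99 ± 0.156 to 7.51 ± 1.27 CPM (log2 fold change 1.33 ± 0.18, adjusted p = 0.039). Cox6b2 (ENSMUSG00000051811, chromosome 7), an isoform of a cytochrome c oxidase subunit best known from testis, rose from 1.71 ± 0.524 to 6.23 ± 0.875 CPM (1.85 ± 0.24, adjusted p = 0.039). At an unadjusted p under 0.05 there were 578 genes higher and 557 lower, 1135 in all, where chance gives 822. Of all genes tested, 12.5% had no overlap between the groups, where chance gives 10%. DESeq2 called 43 genes, 19 higher and 24 lower, and limma-voom called 0, with 1111 genes at an unadjusted p under 0.05. A fit to these groups alone called 18, no low-count filter gave 9 and robust estimation off gave 2. The count was 0 without control replicate 1, shRNA A replicate 1, shRNA A replicate 2 or shRNA A replicate 3, 1 without control replicate 2, 8 (2 higher and 6 lower) without control replicate 3 and 10 (8 higher and 2 lower) without shRNA B replicate 2.

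The p53 and cell death list passed camera's test with shRNA A, with a median log2 fold change of 0.18 (camera adjusted p = 5.5e-14, adjusted p = 0.0965 with an estimated correlation, fry adjusted p = 0.0642). Of 24 tested members, 19 had a positive log2 fold change and 5 a negative one, 1, Eda2r, rose over all genes tested, and 6 rose adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, was at 10.2 ± 1.74 CPM in controls and 28.3 ± 1.8 CPM with shRNA A (SD, n = 3; log2 fold change 1.48 ± 0.20, edgeR adjusted p = 0.0755 over all genes). Phlda3, a repressor of Akt signalling, and Ccng1, cyclin G1, had log2 fold changes of 0.88 ± 0.14 (adjusted p = 0.126) and 0.55 ± 0.10 (adjusted p = 0.269). The list scores were 0.43, 0.41 and 0.35 in the 3 libraries.

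The interferon response list had 41 of 42 members with a positive log2 fold change with shRNA A, a median of 0.63, and 0 members past edgeR's threshold over all genes or adjusted over the list alone (camera adjusted p = 2.71e-17; adjusted p = 0.514 with an estimated correlation). Its score was 0.83 and 1.02 in shRNA A replicates 1 and 2 and 0.085 in shRNA A replicate 3, within the control values of -0.074 to 0.10. The microglia list, markers of the brain's resident macrophages, had a median of 0.12 with 23 of 25 members positive and 2 higher adjusted over the list alone, C1qc at 0.30 ± 0.078 and Fcer1g (camera adjusted p = 1.93e-06; adjusted p = 0.501 with an estimated correlation). Oligodendrocyte markers had a median of 0.36 (camera adjusted p = 1.96e-06; adjusted p = 0.579 with an estimated correlation) with 0 members called, and their score in controls ranged from -0.44 to 0.25. Precursors of these cells had a median of 0.24 with 2 members, Gpr17 and Vcan, higher adjusted over the list alone (camera adjusted p = 6.04e-06; adjusted p = 0.367 with an estimated correlation). The oligodendrocyte median was 0.193 without control replicate 1 and 0.195 without shRNA A replicate 2, the precursor median 0.133 without shRNA A replicate 3 and the microglia median 0.183 without shRNA A replicate 2.

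Lists lower with shRNA A included meningeal, choroid plexus, CA2 and CA3 and pan-neuronal markers, at camera's preset correlation. The meningeal score was 0.328, -0.401 and 0.073 in the controls, so control replicate 2 lay below shRNA A replicate 3, at -0.309. All 16 meningeal and fibroblast markers had a negative log2 fold change, with a median of -0.46 and 3 members, the collagens Col1a1 and Col1a2 and the retinoic acid enzyme Aldh1a2, lower adjusted over the list alone (camera adjusted p = 3.29e-09; adjusted p = 0.367 with an estimated correlation). Markers of CA2 and CA3 pyramidal cells had a median of -0.13, and 5 members were lower adjusted over the list alone, among them Nptx1, neuronal pentraxin 1, at -0.41 ± 0.085 and the kainate receptor gene Grik4 at -0.44 ± 0.096 (camera adjusted p = 0.000574; adjusted p = 0.367 with an estimated correlation). Without control replicate 2 the camera adjusted p of the CA2 and CA3 list was 0.0725, and its median was -0.22, -0.056 and -0.086 without control replicates 1, 2 and 3. Choroid plexus and ependyma markers had a median of -0.98 (camera adjusted p = 0.000778; adjusted p = 0.537 with an estimated correlation). Without control replicate 3, whose transthyretin transcript Ttr stood at 935 CPM against 1.42 to 16.2 CPM in the other 8 libraries, the choroid median was -0.27 and its camera adjusted p 0.854, and without shRNA A replicate 1 the median was -1.84. Pan-neuronal markers had a median of -0.10 with 19 of 22 members negative and 0 called (camera adjusted p = 0.000264; adjusted p = 0.514 with an estimated correlation); without control replicate 2 the camera adjusted p was 0.119 and the median -0.047. In all, 11 lists were higher and 7 lower with shRNA A, 11 in all without control replicate 3, and 0 passed with an estimated correlation.

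Of the remaining lists past camera's threshold with shRNA A, several calls rested on 1 library. Ribosomal proteins (median 0.09, camera adjusted p = 0.00028; adjusted p = 0.537 with an estimated correlation) did not pass without control replicate 3 (0.0684), and their median was 0.057 there and 0.048 without shRNA A replicate 3. Activity-regulated genes, those that neurons induce when they fire (0.14, camera adjusted p = 0.000551; adjusted p = 0.568 with an estimated correlation), did not pass without control replicate 1 or control replicate 3, with a highest camera adjusted p of 0.0946. Their median was 0.041, 0.237 and 0.071 without control replicates 1, 2 and 3, and 0.073 without shRNA A replicate 3. Presynaptic genes (-0.10, camera adjusted p = 0.000766; adjusted p = 0.537 with an estimated correlation) did not pass without control replicate 2 or shRNA A replicate 1 (highest 0.119), and the median was -0.042 without control replicate 2. Dentate granule cell markers (-0.16, camera adjusted p = 0.0018; adjusted p = 0.606 with an estimated correlation) did not pass without control replicate 3 (0.414), with a median of -0.075 there and -0.26 without control replicate 2. Genes of the mitochondrial respiratory chain (0.06, camera adjusted p = 0.00284; adjusted p = 0.684 with an estimated correlation) and astrocyte markers (0.07, camera adjusted p = 0.0113; adjusted p = 0.606 with an estimated correlation) did not pass without control replicate 3 or shRNA A replicate 3 (highest 0.505 and 0.346). Without these their medians were 0.022 and 0.015 for the respiratory chain and 0.026 and 0.024 for astrocytes, and the first was 0.088 without shRNA A replicate 2. Calmodulin and calcium-dependent signalling genes had a median of -0.04 with Nos1, the neuronal nitric oxide synthase, lower adjusted over the list alone (camera adjusted p = 0.0228; adjusted p = 0.537 with an estimated correlation). They did not pass without control replicate 2 or shRNA A replicate 2 (highest 0.42), with medians of -0.011 and -0.021. Activated microglia genes (0.12, camera adjusted p = 0.0268; adjusted p = 0.606 with an estimated correlation) did not pass without control replicate 1 or shRNA A replicate 2 (highest 0.205), and their median was 0.043, 0.2 and 0.219 without control replicates 1, 2 and 3, and 0.182 without shRNA A replicate 3. Neuropeptide and trophic factor genes (0.11, camera adjusted p = 0.0268; adjusted p = 0.514 with an estimated correlation) did not pass without control replicate 1, control replicate 3, shRNA A replicate 2 or shRNA A replicate 3 (highest 0.117), and their median was 0.212, 0.059 and 0.068 without shRNA A replicates 1, 2 and 3. The other 14 lists did not pass with shRNA A, with medians between -0.041 and 0.11 and camera adjusted p between 0.129 and 0.793.

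With shRNA B, 128 genes rose and 39 fell. Among called genes with a mean of at least 1 CPM and no overlap between the groups, large rises were those of Eda2r and of antiviral genes induced by interferon. Mx1, a dynamin-like GTPase, went from 0.0769 ± 0.0533 CPM, near the level of 3 reads, to 2.85 ± 1.6 CPM (SD, n = 3; log2 fold change 5.15 ± 0.79, edgeR adjusted p = 0.0246). Oasl2, of the oligoadenylate synthetase family, rose from 2.7 ± 0.047 to 31.6 ± 15.6 CPM (3.54 ± 0.57, adjusted p = 0.0454). Ifit1 and Ifi44 rose by log2 fold changes of 3.35 ± 0.56 (adjusted p = 0.0443) and 3.30 ± 0.63 (adjusted p = 0.0482). Eda2r rose again, by 3.31 ± 0.40 (adjusted p = 0.00623). Genes that fell included Htr2c, the serotonin 2C receptor, from 17.7 ± 4.08 to 6.21 ± 2.04 CPM (log2 fold change -1.51 ± 0.23, adjusted p = 0.0239). The collagen gene Col15a1 (-1.03 ± 0.15, adjusted p = 0.0111), Slc6a13, a GABA transporter of the meninges (-0.98 ± 0.19, adjusted p = 0.0376), and Gpc3, glypican 3 (-0.93 ± 0.16, adjusted p = 0.0239), fell too. At an unadjusted p under 0.05 there were 2110 genes where chance gives 822. Of all genes tested, 18.1% had no overlap between the groups, where chance gives 10%. Of the 167 called genes, 48 belong to a list, 24 of them to the interferon list.

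Among genes with the firmest calls, B2m, the light chain of MHC class I and a member of the interferon list, rose from 55.3 ± 3.73 to 124 ± 24.4 CPM (SD, n = 3; log2 fold change 1.16 ± 0.12, edgeR adjusted p = 0.0061). It passed in all 19 alternatives run on it, as did Ephx1 (0.97 ± 0.099), Cdkn1a (1.94 ± 0.20), Eda2r, the intermediate filament gene Vim (1.13 ± 0.12) and C1qc (0.61 ± 0.078). DESeq2 called 386 genes, 224 higher and 162 lower, limma-voom 95, and a fit to these groups alone 42. The count for shRNA B was 13, 23 and 19 without control replicates 1, 2 and 3, 103 and 98 without shRNA A replicates 1 and 2, and 62 without shRNA B replicate 2.

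The interferon response list rose as a group with shRNA B. All 42 tested members had a positive log2 fold change, 24 rose over all genes tested and 41 adjusted over the list alone, with a median of 1.69 (camera adjusted p = 2.85e-92; adjusted p = 0.0625 with an estimated correlation; fry adjusted p = 0.024). Ifih1, the RNA sensor MDA5, rose by a log2 fold change of 1.59 ± 0.22, Rtp4 by 2.25 ± 0.33 and Ifit3 by 2.47 ± 0.33, with edgeR adjusted p = 0.0109, 0.0167 and 0.0207. The list scores were 1.32, 2.5 and 1.75 in the 3 libraries. Microglia markers moved in the same libraries. Of 25 tested, 23 had a positive log2 fold change, 5 rose over all genes and 16 adjusted over the list alone. Among the 5 were the complement genes C1qa (0.66 ± 0.09), C1qb (0.62 ± 0.099) and C1qc and the protease gene Ctss (0.62 ± 0.10). Their median was 0.28 (camera adjusted p = 3.9e-18; adjusted p = 0.0823 with an estimated correlation). Of 23 genes of activated microglia, Itgax (2.50 ± 0.36), Cst7 (3.00 ± 0.53), Tlr2 (1.43 ± 0.27) and Ccl12 (2.76 ± 0.55) rose over all genes. The list had a median of 0.65 with 13 members higher adjusted over the list alone (camera adjusted p = 2.99e-16; adjusted p = 0.0823 with an estimated correlation).

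Genes of reactive astrocytes, the state these glia take after injury, had a median of 0.25 with shRNA B. Of 30 tested, 4 rose over all genes: Vim, the immunoproteasome gene Psmb8 (1.17 ± 0.21, edgeR adjusted p = 0.0262), which is counted in the interferon list too, and the complement genes C4b (1.34 ± 0.21, adjusted p = 0.0323) and C3 (2.50 ± 0.44, adjusted p = 0.0323). Adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 1.37e-10; adjusted p = 0.0625 with an estimated correlation). General astrocyte markers had a median of -0.02 and did not pass (camera adjusted p = 0.912), although Aldh1l1, a folate enzyme of astrocytes, rose by 0.47 ± 0.07 (adjusted p = 0.0137). The p53 list had 5 of 24 members risen over all genes, Cdkn1a, Eda2r, Ccng1 (0.74 ± 0.10, adjusted p = 0.0109), Phlda3 (1.09 ± 0.14, adjusted p = 0.0109) and, named outside the rule, Pmaip1. Adjusted over the list alone 10 rose and 1 fell, with a median of 0.21 (camera adjusted p = 2.04e-13; adjusted p = 0.0625 with an estimated correlation; fry adjusted p = 0.0159). The median of the p53 list was 0.128 without shRNA B replicate 2.

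Several neuronal lists were lower with shRNA B at camera's preset correlation, while the excitatory postsynaptic scaffold, potassium channels and CA2 and CA3 markers did not pass. Pan-neuronal markers had a median of -0.13 with 21 of 22 members negative and 0 called (camera adjusted p = 1.93e-05; adjusted p = 0.247 with an estimated correlation), and the median was -0.086 without control replicate 2. Calmodulin and calcium-dependent signalling, the group closest to the name of Camta1, had a median of -0.10 with 31 of 38 members negative. Atp2b3, a plasma membrane calcium pump, fell by 0.37 on the log2 scale (SE 0.072, edgeR adjusted p = 0.0361). In that list 3 members fell adjusted over the list alone (camera adjusted p = 0.000185; adjusted p = 0.218 with an estimated correlation), and its median was -0.055 without control replicate 2. Glutamate receptors had a median of -0.13 with 18 of 24 members negative, 0 called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00723; adjusted p = 0.0847 with an estimated correlation; fry adjusted p = 0.000911). GABA receptors and inhibitory postsynaptic genes had a median of -0.09 with 17 of 18 negative (camera adjusted p = 0.00997; adjusted p = 0.218 with an estimated correlation). Neuropeptide and trophic factor genes had a median of -0.14, and the secretogranin gene Scg2 fell, with a log2 fold change of -0.40 ± 0.084 (edgeR adjusted p = 0.045; list camera adjusted p = 0.0106; adjusted p = 0.247 with an estimated correlation). Without control replicate 2 or shRNA B replicate 2 that list did not pass, with a highest camera adjusted p of 0.0865, and its median was -0.075 without the latter. Presynaptic genes had a median of -0.10 (camera adjusted p = 0.00295; adjusted p = 0.416 with an estimated correlation). Without control replicate 2 their camera adjusted p was 0.12, and without shRNA B replicate 1 their median was -0.047. Interneuron markers had a median of -0.12 (camera adjusted p = 0.000185; adjusted p = 0.247 with an estimated correlation) and without shRNA B replicate 1 a camera adjusted p of 0.076 and a median of -0.076. Of these lower lists only glutamate receptors passed fry. The fry adjusted p was 0.119 for pan-neuronal, 0.0811 for calmodulin and 0.0577 for GABA receptor genes. It was 0.119 for neuropeptide, 0.232 for presynaptic and 0.119 for interneuron genes.

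Of the remaining lists, meningeal and fibroblast markers had a median of -0.52 with shRNA B, and 1, Slc6a13, of 16 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 8.83e-06; adjusted p = 0.247 with an estimated correlation). The meningeal median was -0.321 without control replicate 1. The groups overlapped, since the meningeal score was -0.401 in control replicate 2 and -0.235 in shRNA B replicate 1. Ribosomal protein genes had a median of 0.13 with 40 of 48 positive and 0 called (camera adjusted p = 2.8e-05; adjusted p = 0.363 with an estimated correlation), and the median was 0.076 without control replicate 3. In sodium and calcium channels Cacna2d1, an auxiliary calcium channel subunit, fell by 0.41 on the log2 scale (SE 0.074, edgeR adjusted p = 0.0259), and the list's median was -0.09 (camera adjusted p = 0.0132; adjusted p = 0.343 with an estimated correlation). That list did not pass without control replicate 2, control replicate 3 or shRNA B replicate 1, with a highest camera adjusted p of 0.152. Dentate granule cell markers had a median of -0.13 (camera adjusted p = 0.0132; adjusted p = 0.67 with an estimated correlation). Without control replicate 3 or shRNA B replicate 3 they did not pass (highest camera adjusted p = 0.615), and their median was -0.31 and -0.069 without control replicates 2 and 3, and -0.217, -0.239 and 0.02 without shRNA B replicates 1, 2 and 3. Oligodendrocyte markers had a median of 0.21 (camera adjusted p = 0.0214; adjusted p = 0.799 with an estimated correlation) and did not pass without control replicate 1, shRNA B replicate 1 or shRNA B replicate 3 (highest camera adjusted p = 0.923). The oligodendrocyte median was 0.065 and 0.344 without control replicates 1 and 2, and 0.42 and 0.043 without shRNA B replicates 2 and 3. Red blood cell transcripts had a median of 0.30, with Hba-a1 and Hba-a2 higher adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.247 with an estimated correlation), and did not pass without control replicate 3 or shRNA B replicate 3 (highest camera adjusted p = 0.117), with a median of 0.189 without the latter.

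The lists that did not pass with shRNA B included some that passed with shRNA A, and those differences were not all past the test between the shRNAs. Choroid plexus and ependyma markers had a median of -0.95 (camera adjusted p = 0.0902) and oligodendrocyte precursor markers one of 0.11 (camera adjusted p = 0.119). CA2 and CA3 markers had a median of -0.03 (camera adjusted p = 0.994), mitochondrial respiratory chain genes 0.005 (camera adjusted p = 0.676) and activity-regulated genes -0.03 (camera adjusted p = 0.752). CA1 pyramidal cell markers (-0.14, camera adjusted p = 0.162), neocortex markers (-0.12, 0.313), thalamus and habenula markers (-0.04, 0.912) and endothelial and mural markers (-0.02, 0.935) did not pass. Neither did potassium and HCN channels (-0.02, 0.313), the excitatory postsynaptic scaffold (0, 0.752), microRNA machinery (0.007, 0.912) or extracellular matrix and perineuronal net genes (0.04, 0.803), of which Mmp2 rose.

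**Figure D2:**
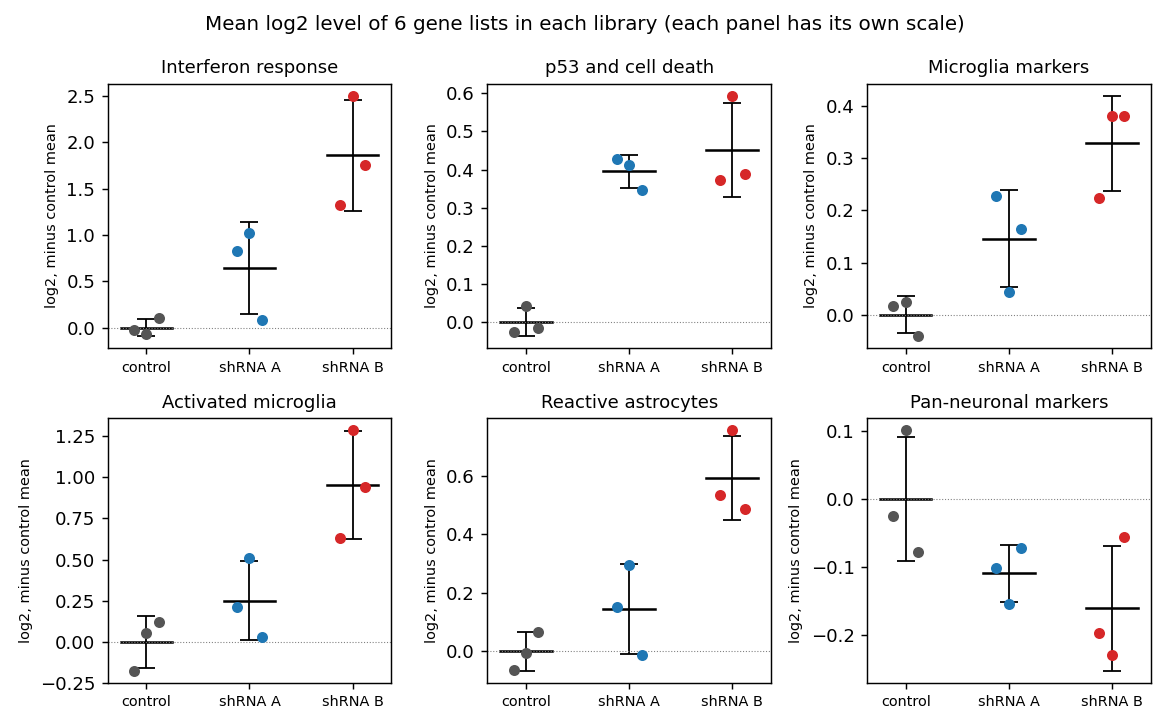
Scores of 6 gene lists, the mean log2 CPM of a list minus the control mean (vertical axis, log2, a scale of its own in each panel), in each library of the 3 groups (points, spread sideways), with mean (line) and SD (bars, n = 3). The interferon score is 1.32 to 2.5 with shRNA B and 0.085 to 1.02 with shRNA A, while the p53 score is 0.35 to 0.43 with shRNA A and 0.37 to 0.59 with shRNA B.

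Genes changed by both shRNAs, the comparison that asks for effects not tied to a single hairpin, were Ephx1, Eda2r, Mmp2 and Cox6b2. These 4 rose with each shRNA and 0 genes fell with both. With shRNA B the log2 fold changes of Mmp2 and Cox6b2 were 1.02 ± 0.18 (edgeR adjusted p = 0.0255) and 1.47 ± 0.25 (adjusted p = 0.0239). Lists drawn independently would share 0.0311 genes, and unchanged groups sharing the controls shared 0.05 on average and at most 1 in 60 simulations. No gene was changed in these simulations, so few shared calls could arise there. They do not show how many calls the shared controls would add between shRNAs that each change genes. At an unadjusted p under 0.05 both shRNAs shared 444 genes, 211 higher and 233 lower, against 165 (133 to 199) in the simulations and 72.8 for independent lists. Across genes, which are not independent replicates, the log2 fold changes of both shRNAs correlated with Pearson's r of 0.636 and Spearman's rho of 0.504, where the simulations gave 0.503 (0.45 to 0.534) and 0.463. Of 100 splits of the 9 libraries into 3 groups, the real one included, 8 gave a Pearson's r at least as high, with 0.802 as the highest other. The covariance was 0.0533 against 0.0194, a difference of 0.0339, and 68.5% of genes had the same sign against 66.7%. The 3 controls were not divided between the shRNAs. The simulations share the controls but draw each gene independently, so part of the excess may still come from the shared controls. DESeq2 shared 23 genes, 12 higher and 11 lower with both. The number was 0 with limma-voom, 7 (6 higher and 1 lower) with no low-count filter and 2 with robust estimation off. It was 0 without control replicate 1 or any of shRNA A replicates 1, 2 and 3, 1 without control replicate 2, 2 (1 higher and 1 lower) without control replicate 3 and 7 (5 higher and 2 lower) without shRNA B replicate 2.

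**Figure D3:**
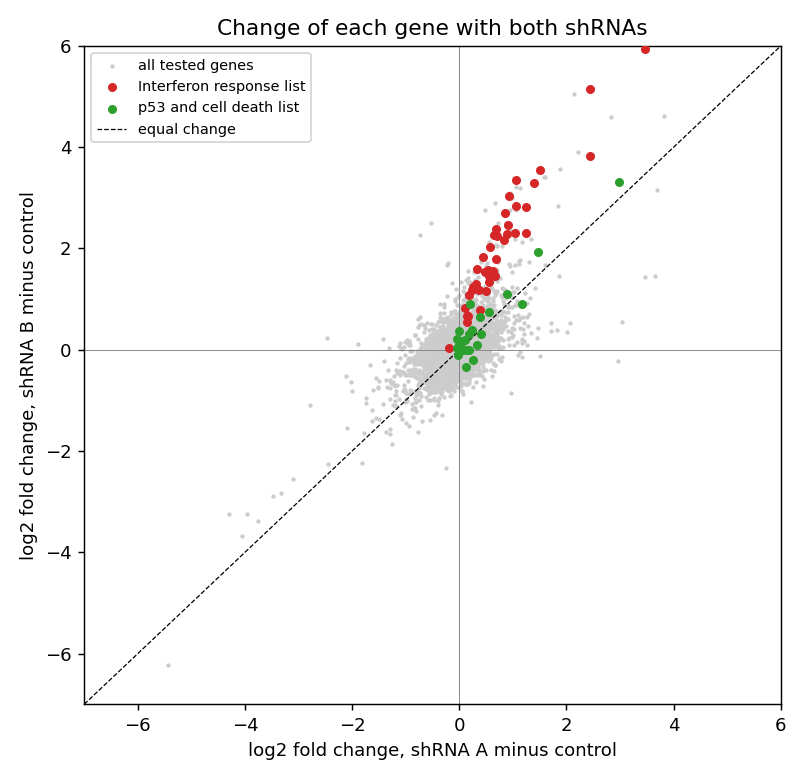
Log2 fold change of each tested gene with shRNA A (horizontal axis) and shRNA B (vertical axis), each minus control, with members of the interferon list in red, those of the p53 list in green and equal change as a dashed line. Interferon genes lie above the dashed line, with medians of 0.63 and 1.69, and p53 genes lie nearer to it, with medians of 0.18 and 0.21.

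The mean of both shRNAs against control called 16 genes, 12 higher and 4 lower. Of these, 4 were also called with shRNA A and 15 with shRNA B. Ephx1 (log2 fold change 0.89 ± 0.088, edgeR adjusted p = 0.0044), Eda2r (3.14 ± 0.38), Mmp2 and Cox6b2 were among the higher genes. The other genes of this contrast were chosen after their values were seen. They include Cdkn1a (1.71 ± 0.18, adjusted p = 0.0201), Phlda3 (0.99 ± 0.13, adjusted p = 0.0214), Ccng1 (0.64 ± 0.092), B2m (0.83 ± 0.11), C1qc (0.45 ± 0.069), Mapkapk3 and the retinaldehyde dehydrogenase Aldh1a1, all higher. The 4 lower genes include Col15a1 (-0.93 ± 0.13), the myosin gene Myo5b (-0.60 ± 0.087, adjusted p = 0.0231) and Parva, which was called in neither contrast alone (-0.35 ± 0.056, adjusted p = 0.0473). Lists past camera's threshold numbered 8 higher and 7 lower. The p53 list had a median of 0.17 with 4 of 24 members called and 8 higher adjusted over the list alone (camera adjusted p = 2.14e-16; adjusted p = 0.0697 with an estimated correlation). Its score was above all 3 controls in all 6 knock-down libraries (exact two-sided permutation p = 0.0119, the smallest possible, adjusted p = 0.242 over the 32 lists). DESeq2 called 243 genes, 138 higher and 105 lower, and 67 were called with no low-count filter. The 18 genes called without control replicate 3 were 4 higher and 14 lower, and 7 of them were shared with the 16. The count was 1 and 2 without control replicates 1 and 2, 3, 1 and 6 without shRNA A replicates 1, 2 and 3, and 52, 36 and 23 without shRNA B replicates 1, 2 and 3.

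Between the shRNAs, interferon and glial activation genes were higher with shRNA B. All 42 interferon genes had a higher level with shRNA B, by a median log2 difference of 1.08, and 38 were higher adjusted over the list alone (camera adjusted p = 2.39e-57; adjusted p = 0.114 with an estimated correlation). Genes of activated microglia (median 0.58, 8 of 23 higher adjusted over the list alone) and reactive astrocytes (median 0.23, 7 of 30) went the same way, with camera adjusted p = 5.81e-13 and 8.11e-10; adjusted p = 0.114 with an estimated correlation in both. The interferon and reactive astrocyte lists share genes, Psmb8 among them, and are not separate evidence. The interferon median was 0.693 without shRNA B replicate 2, and that of activated microglia 0.317 without this library and 0.346 without shRNA A replicate 3. Neuropeptide and trophic factor genes were lower, with a median of -0.22 (camera adjusted p = 2.62e-07; adjusted p = 0.114 with an estimated correlation), and Scg2 differed by -0.44 ± 0.084. The p53 list did not pass, with a median of 0.09 (camera adjusted p = 0.187). Camta1 itself differed by -0.02 ± 0.21 (SE, edgeR adjusted p = 0.987), a fitted difference smaller than its error. No single gene passed: edgeR called 0 genes with 1536 at an unadjusted p under 0.05, where chance gives 822, limma-voom called 0, and DESeq2 called 123. The smallest adjusted p was 0.0905, shared by 12 genes that include, chosen after their values were seen, Vim (1.02 ± 0.12) and C3 (3.02 ± 0.47). Without shRNA B replicates 1, 2 and 3 edgeR called 38 (35 higher and 3 lower with shRNA B), 1 and 110 (30 higher and 80 lower) genes, and no low-count filter gave 21. Without shRNA B replicate 3 the lists past camera's threshold numbered 23, against 15 with all libraries.

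In the authors' deposited table, 379 of 15093 genes with an adjusted p have one below 0.05 in a likelihood ratio test over the 3 groups. Of these, 196 are higher with both shRNAs, 127 lower with both and 56 of opposite sign, by the fold changes of the authors' deposited table. The same kind of DESeq2 test on the deposited counts called 379 genes, 359 of them shared with the authors' deposited table. An edgeR test over the 3 groups called 78, with 75 shared.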

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

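The tests of explanations for the interferon and p53 patterns were chosen only after the results were seen, and the splits of the libraries were planned.

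The test between the shRNAs singled out 15 lists, in which shRNA B and shRNA A differed at camera's preset correlation, and 0 of them passed with an estimated correlation. The median log2 difference of shRNA B minus shRNA A was 1.082 for the interferon response (camera adjusted p = 2.39e-57; adjusted p = 0.114 with an estimated correlation), 0.576 for activated microglia (5.81e-13; 0.114) and 0.226 for reactive astrocytes (8.11e-10; 0.114). It was 0.133 for microglia markers (2.62e-07; 0.298) and -0.216 for neuropeptides and trophic factors (2.62e-07; 0.114). Activity-regulated genes had -0.152 (0.000235; 0.419) and glutamate receptors -0.081 (0.00522; 0.114). With 1 library left out, the interferon median was 0.693 without shRNA B replicate 2, that of activated microglia 0.346 without shRNA A replicate 3 and 0.317 without shRNA B replicate 2, and that of glutamate receptors -0.136 without shRNA A replicate 3.

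The other differences did not pass without 1 library. Interneuron markers had a median difference of -0.113 (camera adjusted p = 0.000638; adjusted p = 0.357 with an estimated correlation), CA2 and CA3 markers 0.195 (0.00215; 0.278) and CA1 markers -0.282 (0.00222; 0.357). Without shRNA B replicate 1 their camera adjusted p were 0.15, 0.102 and 0.0661 and their medians -0.023, 0.086 and -0.101. The interneuron and CA1 medians were -0.187 and -0.506 without shRNA B replicate 3, and that of CA2 and CA3 was 0.128 without shRNA A replicate 3. GABA receptors and the inhibitory postsynapse had -0.079 (0.00737; 0.252), and 0.117 without shRNA A replicate 1. Astrocyte markers had -0.09 (0.0122; 0.546) and oligodendrocyte precursor markers -0.11 (0.0339; 0.419), and did not pass without shRNA A replicate 3 or shRNA B replicate 2 (highest 0.394 and 0.501), where the medians were -0.037 and 0.001 for astrocytes and -0.055 and -0.023 for precursors. The precursor median was -0.168 without shRNA A replicate 1 and -0.167 without shRNA B replicate 3. Sodium and calcium channels had -0.061 (0.0457; 0.419), and did not pass without shRNA A replicate 1 or shRNA B replicate 1 (highest 0.292), with medians of 0.002 and -0.013. Calmodulin and calcium-dependent signalling had -0.034 (0.0495; 0.419), and did not pass without shRNA A replicate 1, shRNA A replicate 3 or shRNA B replicate 1 (highest 0.325). Its median was -0.053 and -0.057 without shRNA A replicates 2 and 3, and -0.022 without shRNA B replicate 1.

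The interferon list was higher with shRNA B than with shRNA A at camera's preset correlation (adjusted p = 0.114 with an estimated correlation; 0 of 42 members called by edgeR over all genes, 38 adjusted over the list alone), although both lowered Camta1 to a like extent. More microglia in the tissue would raise their markers as much. However, relative to control the interferon score exceeded the microglia score by 1.53 (SD 0.531, 1.1 to 2.12 in the 3 shRNA B libraries). Relative to shRNA A, the mean interferon score with shRNA B was higher by 1.212 and the mean microglia score by 0.184. The extent of the Camta1 loss stays open: in the 5 pairs in which an shRNA B library had more Camta1 left than an shRNA A library, its score was higher by 0.819 on average (0.294 to 1.66), against what a graded loss predicts, but these pairs hold only 2 shRNA B libraries and the SD within the shRNA groups was 0.55. Other values have the sign that a graded loss predicts. Over the 6 knock-down libraries the interferon score and log2 Camta1 had Pearson's r = -0.558 (exact permutation p = 0.275). Centred within each shRNA r was -0.84 (exact permutation p = 0.111, adjusted p = 0.148 over 4 relations). Without shRNA B replicate 2 and shRNA A replicate 2 the uncentred r was 0.224 (exact permutation p = 0.792). These relations cannot tell the Camta1 loss from the amount of virus in the tissue, which was not measured here. A single extreme library stays open, since without shRNA B replicate 2 the difference was 0.889 (SE 0.403, 95% interval -0.393 to 2.17). A response to the sequence of the hairpin or to the virus preparation may also differ between the shRNAs, and was not tested.

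The p53 list was higher with both shRNAs at camera's preset correlation (adjusted p = 0.0965 and 0.0625 with an estimated correlation for shRNA A and shRNA B). A linear dependence on the interferon response would bring its score to the control level at an interferon score of 0, but there the fit over the 6 knock-down libraries gave 0.319 (SE 0.0489, 95% interval 0.184 to 0.455), above the highest control, 0.042; a dependence of another shape stays open. A dependence on the extent of the Camta1 loss stays open: over the 6 knock-down libraries the score and log2 Camta1 had Pearson's r = -0.845 (exact permutation p = 0.0333, adjusted p = 0.133 over 4 relations computed) and Spearman's rho = -0.771 (exact permutation p = 0.103, adjusted p = 0.222). Without shRNA B replicate 2 and shRNA A replicate 2 r was -0.509 (exact permutation p = 0.542). The 4 left are few and span less of the Camta1 range, so this cannot show whether the relation rests on those libraries. Centred within each shRNA r was -0.878 (exact permutation p = 0.111). Here too the amount of virus in the tissue was not measured and cannot be told apart from the Camta1 loss. The control libraries carried an shRNA too, but none was directed against another gene, so a response to a hairpin that engages a target, or to other targets of the hairpins, cannot be told apart from one to the Camta1 loss.

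For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split with shRNA A called 4 genes, reached by 1 of the 10, with 0 as the highest other, and 18 lists, reached by 1 of the 10, with 16 as the highest other. Each count of splits includes the real one. The real split with shRNA B called 167 genes, reached by 1 of the 10, with 1 as the highest other, and 18 lists, reached by 2 of the 10, with 18 as the highest other. Between the shRNAs 10 of the 10 splits called at least 0 genes by edgeR, the real value and the highest other, and 3 of the 10 called at least the real 15 lists, with 17 as the highest other. At an unadjusted p under 0.05 the real split between the shRNAs had 1536 genes, and DESeq2 called 123 and limma-voom 0.

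For the mean of both shRNAs, 2 of 84 splits into 3 and 6 libraries called at least the real 16 genes. This excludes at 0.05 only that the libraries were assigned by chance, and the highest other called 42. That split set the 3 shRNA B libraries against the rest and points to a structure of the samples, the separation of shRNA B. For lists, 28 of 84 splits called at least the real 15, with 25 as the highest other, so chance is not excluded. The 6 libraries of each other split were put at random into 2 groups of 3. For genes changed by both shRNAs, 1 of 100 splits into 3 groups gave the real 4, with 1 as the highest other. This excludes at 0.05 only that all libraries were assigned to the groups by chance. The other splits mix the separate shRNA B libraries with the rest. They therefore do not test whether groups that differ share calls by chance or through the shared controls. For the correlation of both effects, 8 of 100 splits gave at least the real 0.636, with 0.802 as the highest other, so chance is not excluded.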

How the results depend on the processing

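The exact permutation of list scores was chosen only after the results were seen; the other alternatives were planned. Of 245 gene results, 188 to 230 kept their direction and side of the threshold with 1 library left out, and 190 to 245 under the other alternatives. Of 66 list results, 54 to 63 did so with 1 library left out and 65 or 66 under RLE scaling or the replicate block, but 0 with an estimated correlation. Many of the gene results were not called in the main fit and kept their side by staying uncalled. Called gene results that no longer passed numbered 54, 46 and 44 without control replicates 1, 2 and 3. The 190 came from the fit to the groups compared alone, which was not run for the mean of both shRNAs. The cause of the changes below was not tested, except that leaving out a library leaves fewer samples and a looser adjusted p calls more. Genes near the level of 3 reads, 0.0786 to 0.103 CPM, are limited by depth. The alternatives for normalized values were not run because counts were deposited.

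With no low-count filter 9 genes were called for shRNA A, 67 for the mean, 21 between the shRNAs and 7 for both. DESeq2 called 43 for shRNA A, 386 for shRNA B, 243 for the mean, 123 between the shRNAs and 23 for both. Limma-voom called 0 for shRNA A, where 1111 genes had an unadjusted p under 0.05, 95 for shRNA B and 0 for both, and edgeR fits to the groups compared alone called 18 for shRNA A and 42 for shRNA B. With robust estimation off 2 genes were called for shRNA A and 2 for both. At an adjusted p of 0.1 there were 299 for shRNA B, 44 for the mean and 12 between the shRNAs.

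Camta1 passed with DESeq2 at log2 fold changes of -1.007, -1.026 and -1.017 for shRNA A, shRNA B and the mean. It passed with the groups compared alone at -1.011 for shRNA A, with limma-voom at -1.072 for shRNA B, and with robust estimation off at -1.025 for shRNA B and -1.016 for the mean. With 1 library left out it lay between -1.125 and -0.864 for shRNA A, -1.199 and -0.805 for shRNA B, and -1.103 and -0.906 for the mean.

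With an estimated correlation 0 lists passed in each of the 4 contrasts; fry called 0 for shRNA A, 6 for shRNA B, 2 for the mean and 3 between the shRNAs, and the exact permutation called 0 for the mean. With 1 library left out camera called 11 (without control replicate 3) to 19 lists for shRNA A, 15 to 21 for shRNA B, 14 to 21 for the mean and 12 to 23 (without shRNA B replicate 3) between the shRNAs.

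With 1 library left out, genes called numbered 0 (without control replicate 1 or any of shRNA A replicates 1, 2 and 3) to 10 (without shRNA B replicate 2) for shRNA A. They numbered 13 (without control replicate 1) to 217 (without shRNA B replicate 1) for shRNA B and 1 (without control replicate 1 or shRNA A replicate 2) to 52 (without shRNA B replicate 1) for the mean. Between the shRNAs they numbered 0 (without any control or shRNA A library) to 110 (without shRNA B replicate 3), and for both 0 (without control replicate 1 or any shRNA A library) to 7 (without shRNA B replicate 2).

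Some log2 values changed sign. Fbxl4 with shRNA B was 0.003 with library size only. With 1 library left out it ran from -0.063 to 0.024 (without shRNA B replicate 2), and for the mean from -0.015 (without shRNA B replicate 3) to 0.028. Camta2 ran from -0.077, -0.095 and -0.086 (shRNA A, shRNA B and mean, each without control replicate 1) to 0.157, 0.141 and 0.149. Nppa with shRNA B ran from -0.024 (without shRNA B replicate 1) to 0.327, and Ttr from -7.011 to 0.314 (without control replicate 3). The median of the dentate list with shRNA B ran from -0.31 to 0.024 (without shRNA B replicate 3). That of the choroid list for the mean ran from -1.286 to -0.092 (without control replicate 3), where the test's direction turned.

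Replicate numbers did not pair the libraries over all 3 groups. Of 9 pairs with the same number, 2 had deviations correlated by over 0.1 (-0.128 to 0.273). Of 9 libraries, 5 correlated best with one of their own number, 0 in both other groups, a hint from the data and not the design. Between shRNA A and shRNA B, pairs with the same number had 0.108, 0.089 and 0.273, and those with unlike numbers -0.202 to 0.1. A pairing of these 2 groups is therefore not excluded. With a replicate block 31 genes were called for the mean, 1 between the shRNAs, 5 for shRNA A, 148 for shRNA B and 4 for both, and Camta1 passed at -1.075 for shRNA B and -1.057 for the mean.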

Other observations

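The genes named beside the p53 list, those of MHC class I and complement, and Per2 and Cry1 were chosen after their values were seen. The test of the other clock genes was written before those genes were looked at as a group. Of these, Per1 also belongs to the list of activity-regulated genes.

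Several genes outside the lists rose with shRNA B beside the p53 list. They were picked from 119 called genes that belong to no list, and they were not tested as a group. Aen, a nuclease induced by p53, had a log2 fold change of 0.40 ± 0.08 (SE, edgeR adjusted p = 0.0423), and Gtse1, a regulator of p53 in the cell cycle, one of 2.07 ± 0.32 (adjusted p = 0.016). Lrdd, the death domain gene also called Pidd1, rose by 1.09 ± 0.19 (adjusted p = 0.0239) and Ckap2, a mitotic spindle gene, by 1.23 ± 0.26 (adjusted p = 0.0471). Gdf15, a stress-induced cytokine, rose by 3.15 ± 0.65 (adjusted p = 0.0431) from 0.0535 ± 0.017 CPM, below the level of 3 reads, to 0.522 ± 0.293 CPM (SD, n = 3). With shRNA A none of these 5 genes passed. The log2 fold changes of Aen, Ckap2 and Gdf15 were 0.37 ± 0.08, 1.08 ± 0.26 and 3.69 ± 0.61, with edgeR adjusted p of 0.333, 0.388 and 0.126. Those of Gtse1 and Lrdd were 0.68 ± 0.35 and 0.33 ± 0.20, with adjusted p of 0.744 and 0.764.

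Among members of the interferon list, the MHC class I genes H2-K1 and H2-D1 rose with shRNA B by 1.56 ± 0.24 (edgeR adjusted p = 0.0339) and 1.48 ± 0.21 (adjusted p = 0.0255), and the peptide transporter gene Tap1 by 1.55 ± 0.29 (adjusted p = 0.045). The MHC class I genes H2-T23, a member of the reactive astrocyte list, and H2-Q4 had 1.33 ± 0.28 and 1.79 ± 0.37 and did not pass (adjusted p = 0.0675 and 0.0525), and genes of this family were not tested as a group. The complement protease gene C1ra, in none of the lists, rose by 1.33 ± 0.27 (adjusted p = 0.042). With shRNA A the log2 fold changes of H2-K1, H2-D1 and Tap1 were 0.53 ± 0.25, 0.63 ± 0.21 and 0.63 ± 0.30, with adjusted p from 0.685 to 0.741, and that of C1ra was -0.14 ± 0.30.

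The circadian clock genes Per2 and Cry1 rose with shRNA B, by 0.53 ± 0.07 (edgeR adjusted p = 0.0105) and 0.65 ± 0.092 (adjusted p = 0.0109). A candidate explanation is a different time of day of tissue collection, which would raise other genes of the Per phase and lower those of the Arntl phase. The score of 9 other genes of the first kind minus that of 4 of the second was higher with shRNA B by 0.566 (SE 0.121, 95% interval 0.231 to 0.901), in line with it. None of these genes passed edgeR's test singly. Gm129, named here despite its Gm symbol, had 0.86 ± 0.19 and the smallest edgeR adjusted p, 0.0655. The genes of the first kind did not rise alike. Per1, Per3, Dbp and Bhlhe41 had 0.303, 0.458, 0.566 and 0.358. Tef, Nr1d1 and Nr1d2 had only 0.106 ± 0.072, 0.101 ± 0.093 and 0.105 ± 0.091, and Hlf had -0.094 ± 0.12. Of the second kind, Arntl, Npas2, Clock and Nfil3 had -0.302, -0.341, -0.109 and -0.233. The difference was 0.509, 0.475 and 0.714 in the shRNA B libraries and -0.057, -0.128 and 0.185 in the controls, and shRNA A replicate 3 had 0.557 where the other shRNA A libraries had -0.078 and 0.054. An effect on the clock itself was not tested and stays open.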
